A study of Mus musculus with 6 samples.

How the data were processed

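Bulk RNA sequencing of newborn mouse epidermis was analysed for 6 libraries, 3 labelled control and 3 labelled Hnrnpu knockout. Per the labels' protocols, epidermis was separated from dermis, RNA was extracted with a column kit and libraries were prepared with a TruSeq RNA kit. Each title carries its own number, read here as an animal number, so the libraries are taken as separate animals. By the genotype label, 1 control was wild type and 2 carried the word taken here to mean heterozygous. The deposited matrix has 1 row per sample and 12894 Ensembl gene IDs, and all 6 rows matched 1 sample each.

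The values that the authors deposited are normalized counts, a signal that is never negative. Per the submitters' processing notes, TopHat2 2.1.0, Partek 9.0.20.0202 and the genome build mm39 were used, with no role given for each. The normalization method and the read counting settings are not given in the sources used here. From the values, each library was divided by 1 factor: between 80.8 and 83.3% of its values of up to 20 reads were whole multiples of a step of 0.755 to 1.70, within 0.02 of a step. The rest were fractional, as when reads are shared between genes by estimation, so whole reads were not recovered and no count model was used. Dividing by the step gave an estimated 6460000 to 9120000 assigned reads per library. In the library labelled knockout 2, the shallowest, 1 read was worth 1.70 normalized counts. Sums of normalized counts were 6850663, 7328810 and 7453638 in controls 1 to 3 and 8191409, 10987666 and 8469679 in the libraries labelled knockout 1 to 3, while library medians lay between 130.8 and 138.2. Every gene in the table reached at least 30 estimated reads in some library, so a filter was applied before deposit. An exact 0 is reported as listed at 0. How reads were assigned to strands is not stated, so overlapping and antisense genes cannot be told apart.

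Gene symbols were matched by Ensembl ID for 12771 IDs and 123 IDs had no symbol. The annotation at hand describes another build (GRCm38) than mm39, so it was used for symbols, chromosomes, gene spans and GC content only, and no coordinates are given.

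Values were tested as log2(value + 1), so fold changes are on that scale and understate the change of low genes. Genes above 1 in at least 3 of the 6 libraries were kept (12872). Libraries labelled knockout were compared with controls by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). P-values were Benjamini-Hochberg adjusted over all tested genes at 0.05, and a log2 change of 1 set the 2-fold count. Errors of log2 changes are the moderated SE. Intervals are at 95%. Gene lists were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the 38 lists with at least 3 tested members. Of the 42 fixed lists, those of endothelial cells (2 genes measured), skeletal muscle (1), adipocytes (0), and Schwann and Merkel cells (2) were too short to test. The estimated-correlation form of camera, fry, which tests whether a list's genes move on balance one way, and camera on ranks were also run. The fits and list tests were tested on simulated data for this comparison (12867 genes in the fit). They recovered 24% of 50 genes changed 2-fold, 64% of 50 changed 4-fold, 83.7% of 49 changed 8-fold and 84% of 50 changed 16-fold, with 9 false calls among 12668 unchanged genes. Far fewer genes changed there than passed in the real data (33.6%), which makes the adjusted threshold stricter in the simulation. These shares therefore do not give the power of the real comparison, and smaller changes may still be missed. The 1 changed list was called and 0 of the unchanged ones were. Simulated genes were drawn independently, so this does not check the list test where genes of a list vary together.

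The genes named in the text were chosen by a rule set before the data were examined, as were the lists, the tests and most alternatives. The rule took Hnrnpu, Hnrnpul1, Hnrnpul2 and Xist. It took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, whose mean was at least the median of tested genes, and whose symbols were not predicted or clone names. It took up to 4 members per described list by smallest adjusted p, or the 2 with the highest mean where none passed. Genes outside it (Pck2, Krt1, Krt10, Krt5, the members that moved against their list and those of the further lists under other observations) were chosen after their values were seen.

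The animal numbers in the titles are adjacent across groups (216 with 217, 241 with 242, 250 with 251). Deviations from the group means correlated by 0.37, 0.23 and 0.36 within these pairs and by −0.28 to −0.07 between other libraries of opposite groups. The numbers were therefore taken to pair the libraries, by the data and not by a stated litter. Deviations cancel out within a group, so positive values within pairs bring negative ones elsewhere, and the negative values add no support. The main comparison has no pairing and the fit with pairs as a block is an alternative. The other alternatives were the pseudocount, the filter, median-of-ratios and quantile scaling, the variance model, array weights and leaving out each library. Equal library totals, testing without X and Y genes, and the library labelled knockout 1 alone against the controls were added after seeing the data. Figures were drawn with matplotlib 3.10.9.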

Results

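Epidermis separated from the dermis of newborn C57BL/6 mice (postnatal day 0) was profiled by bulk RNA sequencing, which measures the transcripts of all cells in the sheet together. The 6 libraries came from 3 animals labelled as Hnrnpu knockouts, made with a loxP-Cre system, and 3 controls. By the genotype label, control 1 was wild type, while controls 2 and 3 carried a label read here as heterozygous. Hnrnpu encodes a nuclear matrix and RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family. The values are normalized read counts per gene for 12894 genes. The estimated depth was 9070000, 8280000 and 9120000 assigned reads in controls 1 to 3, and 8770000, 6460000 and 7640000 in the libraries labelled knockout 1 to 3.

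The targeted gene was examined first. Hnrnpu (ENSMUSG00000039630) had 1450, 1318 and 1160 normalized counts in controls 1 to 3 and 1565, 1342 and 1036 in the libraries labelled knockout 1 to 3. The log2 difference was −0.01 ± 0.20 (SE, n = 3 and 3), or 99.4% of the control level with a 95% interval of 72.5 to 136.2% (limma adjusted p = 0.976). An exact two-sided permutation test gave p = 1, where the smallest p that 3 against 3 libraries allow is 0.1. No fall of the gene count was found in the libraries labelled knockout, but the interval allows a level of 72.5% and the permutation test could not have called a fall. The controls are mixed: the wild type control had 1450 normalized counts, and those read as heterozygous a mean of 1239. The gene count sums reads over the whole gene and the labels do not say which part was deleted. It therefore does not check the genotype if the deleted part is small. All directions below go from the libraries labelled control to those labelled knockout and rest on these labels. The paralogs Hnrnpul1 and Hnrnpul2 differed by 0.10 ± 0.17 and 0.36 ± 0.15 on the log2 scale, neither past the threshold (limma adjusted p = 0.676 and 0.0995).

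The groups also differed in sex-chromosome transcripts. Xist, the RNA that silences an X chromosome in female cells, had 5656 and 4758 normalized counts in the libraries labelled knockout 2 and 3, 1.87 in knockout 1, and 0, 0.89 and 3.27 in controls 1 to 3. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were listed at 0 in knockout 2 and 3, while knockout 1 had 323, 194 and 157 normalized counts of them and control 1 had 574, 304 and 233. These 4 genes passed the threshold with all 6 libraries (limma adjusted p = 0.0451 for Xist and 0.033 for Ddx3y). By these transcripts controls 1 to 3 and knockout 1 were male and knockout 2 and 3 female, though the labels give no sex. The changes of these 4 genes therefore reflect mainly that mix of sexes. With knockout 1 alone, Eif2s3y and Kdm5d differed from the controls by −0.736 and −0.767 on the log2 scale. None of the 4 calls was stable. The call of Ddx3y was lost without any single control (adjusted p = 0.0812, 0.0857 and 0.0786 without control 1, 2 and 3) and without knockout 2 or 3 (0.103 and 0.0768), and without the trend (0.0648). Those of Eif2s3y and Kdm5d were lost in the same settings (0.0665 and 0.0645 without the trend) and with knockout 1 alone (0.0748 and 0.0746). That of Xist was lost without any single control (0.115, 0.104 and 0.0813 without control 1, 2 and 3) and without knockout 2 or 3 (0.142 and 0.114), with quantile normalization (0.0553), without the trend (0.0813), with the robust fit (0.0534) and with array weights (0.0571).

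**Figure D1:**
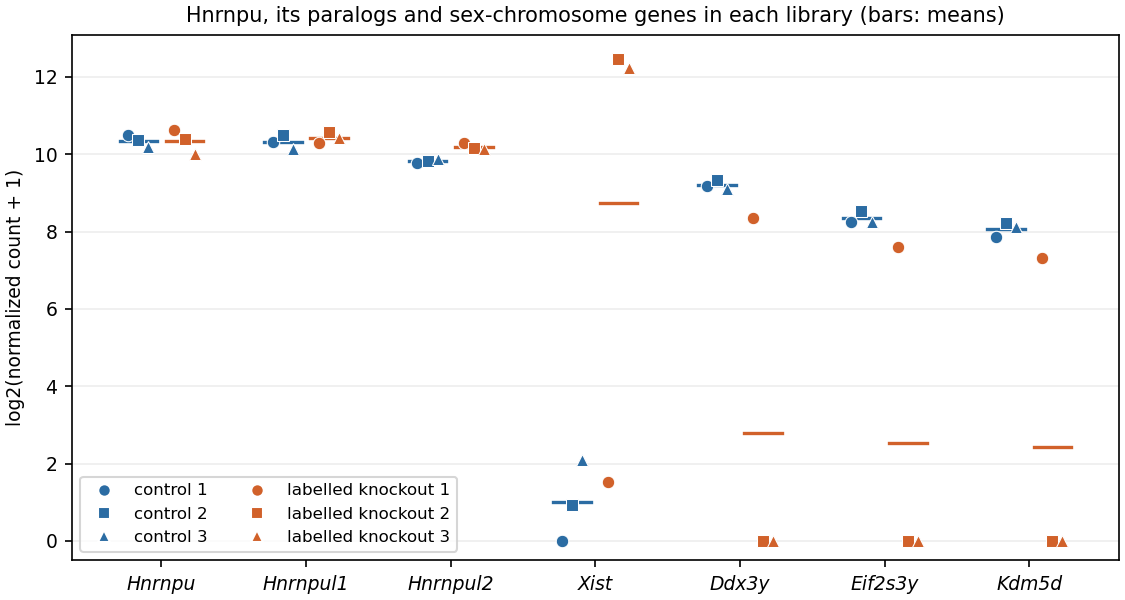
Normalized counts of Hnrnpu, its paralogs and sex-chromosome genes on a log2(normalized count + 1) axis, with 1 symbol per library, controls in blue, libraries labelled knockout in orange and bars at group means of the log2 values. Hnrnpu spans 1160 to 1450 normalized counts in the controls and 1036 to 1565 in the libraries labelled knockout, while Xist separates the libraries labelled knockout 2 and 3 from the other 4.

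The transcriptomes of the groups differed widely. Of 12872 genes tested, 4328 passed the threshold (limma, Benjamini-Hochberg adjusted p of 0.05), 2279 higher and 2049 lower in the libraries labelled knockout. At least 2-fold changes were found for 3067 genes, 1550 higher and 1517 lower. The 3 values of one group lay wholly above those of the other for 50.8% of genes, against 10% by chance. The first principal component held 72.7% of the variance and separated the groups. The count fell to 2682, 2663 and 2631 genes without control 1, 2 or 3, with 1155, 1107 and 1116 of them lower, and 1515 higher without control 3. At least 2-fold lower genes numbered 1011 and 1009 without controls 2 and 3. The library labelled knockout 1, with 1.87 normalized counts of Xist, gave 2711 genes when compared alone with the controls, where the spread comes from the 3 controls only. With the library totals set equal, the split was 1442 higher and 3066 lower, because that scaling moved the median of all genes from −0.02 to −0.36 on the log2 scale. Directions below are relative to a median gene at −0.02.

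Keratins and secreted factors of wounded epidermis led the rises. Krt6a and Krt6b, keratins of wounded and thickened epidermis, were higher by 11.29 ± 0.63 and 10.67 ± 0.62 on the log2 scale (SE, n = 3 and 3; limma adjusted p = 3.79e-05 for both). Krt6a reached 130630, 308020 and 84076 normalized counts in the libraries labelled knockout 1 to 3, from 71.5, 125 and 22.7 in controls 1 to 3. These paralogs are nearly identical and their reads may be split between them, so the share of each is uncertain. Tslp, an epithelial cytokine, went from 0, 0.89 and 0 to 2517, 6316 and 2697 normalized counts, and Slc7a3, a cationic amino acid transporter, from 0.76, 0 and 0 to 1241, 1902 and 934. The alarmin S100a8 was listed at 0 in all 3 controls and had 403, 4682 and 65.4 in the libraries labelled knockout 1 to 3, and its partner S100a9 had 277, 3156 and 86.5 there. Olr1, a scavenger receptor, had 339, 772 and 74.3 there against at most 0.82 in a control. Epgn, an epidermal growth factor receptor ligand, rose by 8.09 ± 0.63, and by 7.31 without knockout 2. The other 4 of the 12 largest rises were the small proline-rich genes Sprr2b, Sprr2e, Sprr2f and Sprr2i. Without control 3, Krt6a rose by 10.61, and Krt6b rose by 10.01 and 11.26 without knockout 2 and 3.

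The largest falls included Skint9, a selection and upkeep of intraepithelial T cells family member, and Krt15, a basal keratin. Skint9 fell by 6.86 ± 0.33 on the log2 scale (limma adjusted p = 1.82e-05), from 1434, 1830 and 2188 normalized counts in controls 1 to 3 to 8.41, 18.7 and 18.9 in the libraries labelled knockout 1 to 3. Krt15 fell by 6.84 ± 0.76 (adjusted p = 6.00e-04), and by 5.81 without knockout 2. The log2 change was −5.38 ± 0.26 for Scd1, a stearoyl-CoA desaturase, −5.74 ± 0.37 for the steroid reductase Akr1d1, −5.71 ± 0.37 for the procollagen protease Adamts14, −5.39 ± 0.35 for the alcohol dehydrogenase Adh6b and −5.25 ± 0.30 for Clca3a2. Wfdc21 changed by −6.04 ± 0.79, or −5.32 and −7.11 without knockout 1 and 2. Dapl1 changed by −5.54 ± 0.63, or −6.39 without knockout 3. The other 3 of the 12 were the Y-linked genes given above, whose falls reflect mainly the mix of sexes. By p-value the first gene was Pck2, a mitochondrial phosphoenolpyruvate carboxykinase, named after its values were seen. It rose by 6.38 ± 0.20 (adjusted p = 5.03e-06).

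**Figure D2:**
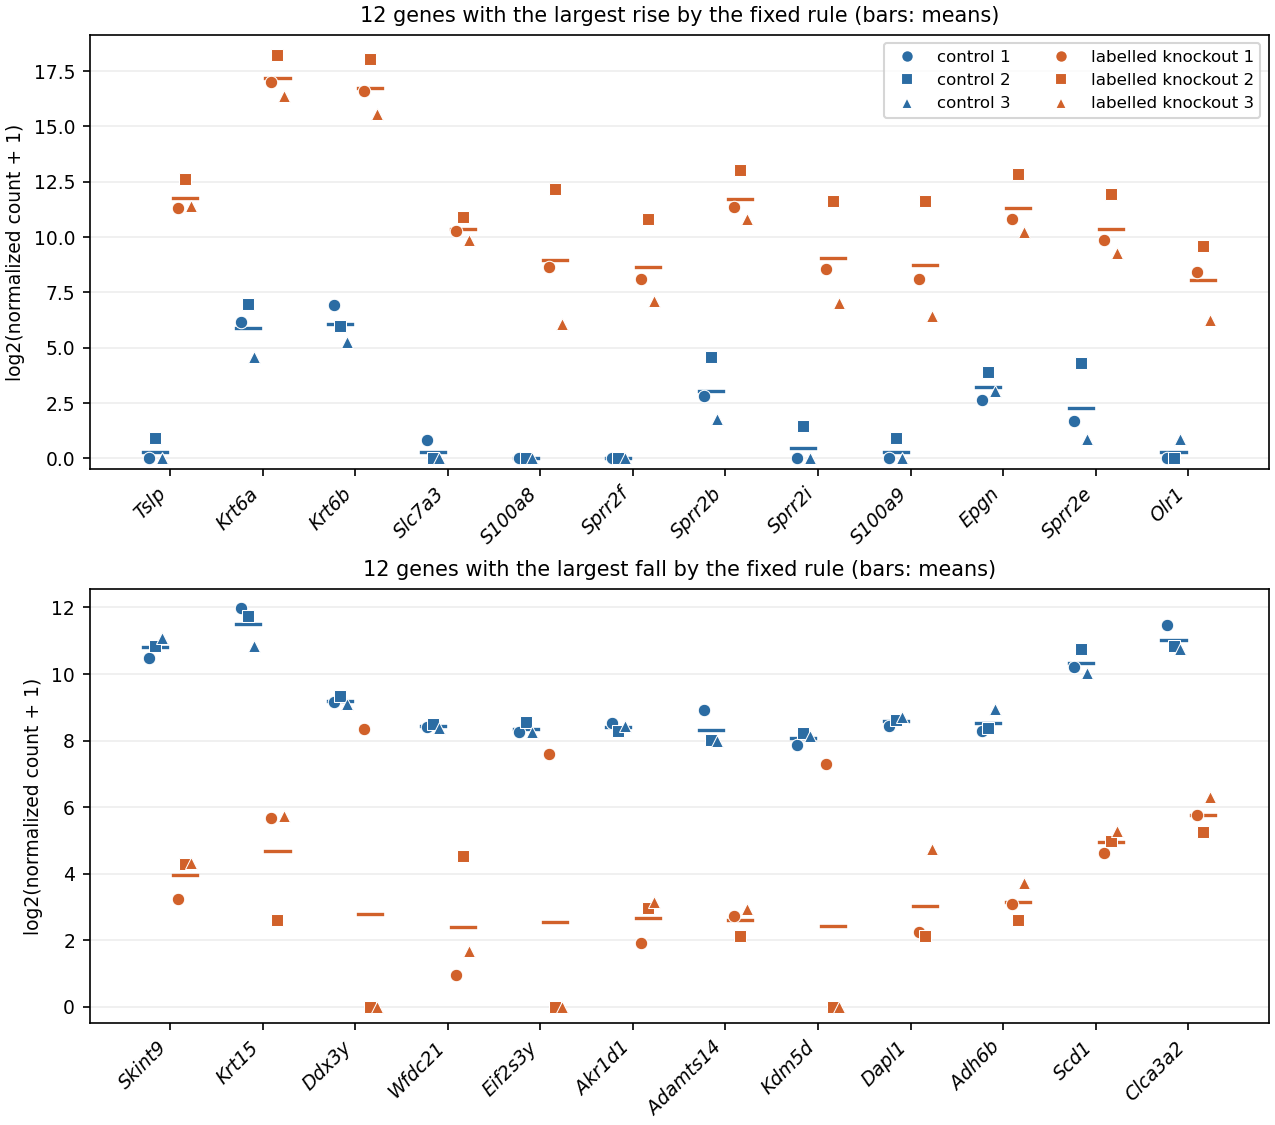
Normalized counts of the 12 genes with the largest rise and the 12 with the largest fall by a rule set beforehand, on a log2(normalized count + 1) axis, with 1 symbol per library, controls in blue, libraries labelled knockout in orange and bars at group means of the log2 values. In 21 of these genes all 3 libraries labelled knockout stand far from the controls, and in Ddx3y, Eif2s3y and Kdm5d the library labelled knockout 1 stands near them.

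Of 42 gene lists fixed beforehand, 38 had at least 3 measured members, and 15 passed the list test (camera with a preset correlation between genes, adjusted p of 0.05), 14 toward higher and 1 toward lower values. None passed with an estimated correlation (camera, smallest adjusted p = 0.59, with 2 lists at an unadjusted p under 0.05), while fry called 16 and camera on ranks 15. Adjusted p with an estimated correlation was 0.59 to 0.77 for each of the 15. The list counts below therefore rest on the tests of single genes.

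Genes of the late epidermal envelope rose as families. All 15 measured small proline-rich genes, which encode cross-linked precursors of the cornified envelope, were higher (15 also adjusted over the list alone), with a median log2 change of 6.55, also 6.55 without 2 members at 0 in a whole group (camera adjusted p = 2.63e-10, and p = 0.60 with an estimated correlation). Sprr2h and Sprr1b rose by 6.55 ± 0.33 and 7.12 ± 0.41. Of 21 late cornified envelope genes, 20 were higher and Lce1m was lower by −1.38 ± 0.25 (the same counts adjusted over the list alone). The median was 2.85, or 2.82 without 2 members at 0 in a whole group (camera adjusted p = 1.72e-13, and p = 0.59 with an estimated correlation). Lce1h rose by 2.94 ± 0.20 and Lce3c by 4.57 ± 0.33. Members of both families share sequence, so the values of single members are uncertain. The wider list of granular layer and cornified envelope proteins did not pass (camera adjusted p = 0.0537), with 11 of 25 members higher and 3 lower (11 and 3 adjusted over the list alone). It passed without control 2, without control 3 and without knockout 1 (0.0414, 0.018 and 0.0206), with fry (0.0458), with a pseudocount of 5 (0.047), with values above 10 in at least 3 samples (0.0495) and with equal library totals (0.0131), where 11 were higher and 10 lower. With quantile normalization 8 were lower. Repetin (Rptn) rose by 5.63 ± 0.38 and the protease inhibitor Spink5 by 2.05 ± 0.24, while Casp14, Flg2 and Hrnr, named because they fell, were lower by −1.14 ± 0.23, −0.97 ± 0.32 and −0.74 ± 0.25. Only 1 member was lower without control 1, 2 or 3 or without knockout 1.

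Stress and wound genes of keratinocytes rose for 22 of 29 measured members and fell for 2, Stfa3 and Serpinb3a (24 and 2 adjusted over the list alone). The median log2 change was 3.34, or 2.63 without 3 members at 0 in a whole group (camera adjusted p = 1.70e-09, and p = 0.60 with an estimated correlation). It was 2.64 without knockout 1 and 1.85 without knockout 2, over the 24 members measured in each. The cytokine Il1a was higher by 3.70 ± 0.24. Of 15 genes of NF-kB signalling and chemokines, 9 were higher and Birc3 was lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00208, and p = 0.60 with an estimated correlation). The Birc3 call was lost without control 1 or 3 (adjusted p = 0.0511 and 0.0595). Nfkbia, an inhibitor of NF-kB, rose by 1.43 ± 0.22, and the alarmin Il33 by 6.79 ± 0.78, or 6.00 and 6.07 without control 3 and knockout 2.

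Targets of the integrated stress response, the program that ATF4 drives when translation is limited, rose for 25 of 27 measured members and fell for 0 (25 adjusted over the list alone). Their median log2 change was 2.13 (camera adjusted p = 4.83e-15, and p = 0.59 with an estimated correlation). Asparagine synthetase (Asns) rose by 4.17 ± 0.19, from 169, 196 and 172 to 2742, 4032 and 3076 normalized counts. The mitochondrial folate enzymes Mthfd2 and Shmt2 rose by 5.45 ± 0.27 and 3.51 ± 0.15 (limma adjusted p = 1.82e-05 for each). Endoplasmic reticulum stress genes rose for 13 of 21 members (15 adjusted over the list alone; camera adjusted p = 5.28e-05, and p = 0.59 with an estimated correlation), among them the chaperone Hspa5 by 2.42 ± 0.28. Heat shock genes rose for 9 of 16 (9 adjusted over the list alone; camera adjusted p = 6.24e-04, and p = 0.62 with an estimated correlation), with heme oxygenase Hmox1 higher by 2.65 ± 0.19.

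Genes raised by p53 were higher for 20 of 32 measured members and lower for Sesn1 (21 and 4 adjusted over the list alone), with a median log2 change of 1.42 (camera adjusted p = 8.59e-05, and p = 0.59 with an estimated correlation). With equal library totals, with adjacent animal numbers as a replicate block and without knockout 1, 3 were lower, and 2 with quantile normalization or without knockout 3. Eda2r rose by 5.97 ± 0.41 and Ccng1 by 2.87 ± 0.21. Sesn2, higher by 2.71 ± 0.24, is also on the integrated stress response list. Cell death machinery did not pass as a list, with 3 of 21 members higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.874). Of these, 1 was higher with equal library totals, without control 3 or without knockout 1, 5 were higher without knockout 3, and 2 were lower without control 1 or 3. Mitotic genes were lower for 13 of 30 members and higher for 0 (17 lower adjusted over the list alone), with a median of −2.01 (camera adjusted p = 4.45e-06, p = 0.75 with an estimated correlation, fry adjusted p = 0.0825). Fewer passed without control 1, control 2 or knockout 2, namely 4, 5 and 5, and 20 with the replicate block, and the median was −1.39 without knockout 2. Top2a, the topoisomerase of dividing cells, fell by 2.14 ± 0.44 and the kinase Ttk by 3.44 ± 0.37. Of 25 DNA replication genes 5 were lower (0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0815). With the replicate block it passed (0.0429), as it did without control 2, control 3 or knockout 1 (0.0447, 0.026 and 0.0124). The members that passed numbered 0 without control 1 or knockout 2, 2 without control 2 or 3, 1 without knockout 3 and 3 with quantile normalization.

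Cytosolic ribosomal protein genes shifted by less, with a median log2 change of 0.49 and 18 of 51 members higher (19 adjusted over the list alone; camera adjusted p = 7.53e-06, and p = 0.75 with an estimated correlation). Only 7 passed without control 1, 2 or 3 and 11 without knockout 2. With equal library totals 7 were higher and 1 lower, and with quantile normalization 10 and 2. Immediate early genes, which respond to handling of tissue, were higher for 12 of 23 (12 adjusted over the list alone; camera adjusted p = 0.00105, and p = 0.60 with an estimated correlation). This count was 7, 6 and 7 without control 1, 2 and 3 and 6 without knockout 2. With equal library totals 7 were higher and 1 lower, and with quantile normalization 7 and 2, where the list missed the threshold (0.0508). Glycolysis and hypoxia genes were higher for 13 of 24 and lower for Pdk1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.0106, and p = 0.77 with an estimated correlation). The list missed the threshold without control 1 (0.0552), without knockout 3 (0.0566), with quantile normalization (0.0588), with fry (0.0641) and with knockout 1 alone (0.0703). Lower members numbered 4 with equal library totals, 3 with the replicate block and 2 with quantile normalization or without knockout 3.

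Of the lists of other cell types, those of melanocytes, dermal fibroblasts, and neutrophils and mast cells passed, all toward higher values. All 12 melanocyte genes were higher (12 adjusted over the list alone), with a median log2 change of 2.90 (camera adjusted p = 1.78e-08, and p = 0.59 with an estimated correlation), and 11 of the 12 exceeded 1 normalized count in all controls. The pigment enzymes Dct and Tyrp1 rose by 2.90 ± 0.20 and 4.36 ± 0.34. Dermal fibroblast genes were measured for 7 of 16 members, of which 5 were higher (5 adjusted over the list alone; camera adjusted p = 0.0129, and p = 0.60 with an estimated correlation). Their levels were low: Col1a2 went from 20.4, 24.8 and 25.3 to 92.5, 61.2 and 75.4 normalized counts, and Col3a1 from 3.02, 29.2 and 8.99 to 122, 182 and 146. Their median log2 change was 2.77, or 3.79 without control 2 and 1.85 without control 3. Of 5 measured neutrophil and mast cell genes 4 were higher (4 adjusted over the list alone; camera adjusted p = 0.0151, and p = 0.60 with an estimated correlation), of which S100a8 and S100a9 are also on the stress and wound list. This call was lost without knockout 1, 2 or 3 (0.0963, 0.132 and 0.213), where 2, 1 and 1 members were higher. S100a8 and S100a9 did not exceed 1 in any control, so they failed the filter there and the list was shorter. Their loss therefore does not show that these 2 genes ceased to be higher. With knockout 1 alone the list median was 2.085. Without control 2 or 3, 2 members were higher. Besides S100a8 and S100a9, the higher members were the receptor gene Cxcr2 and the ligand gene Kitl. The limma call of Cxcr2 was lost without control 1, 2 or 3 (adjusted p = 0.0671, 0.0586 and 0.0661) and without knockout 2 (0.054). The Kitl call was lost without control 2 or 3 (0.0909, 0.0916), without knockout 1 or 3 (0.0881, 0.0514) and with equal library totals (0.101). It was also lost without the trend (0.0553). The list therefore does not show more of these cells. Langerhans cell and macrophage genes did not pass (camera adjusted p = 0.584), with 2 of 15 higher and 2 lower (0 adjusted over the list alone), or 0 and 5 with equal library totals and 2 and 4 with the replicate block. Their median was −0.37, or 0.60 without knockout 1, and with that library alone the list passed toward lower values (camera adjusted p = 0.00301, median −1.48). The 4 calls were each lost without at least 3 of the single libraries. For T cells Cd3e alone passed of 4 genes (1 adjusted over the list alone; camera adjusted p = 0.206), lower by −3.06 ± 0.71, a call lost without control 1 or 2 (0.0516 and 0.0967), and 3 genes were lower without knockout 2. Of 3 red blood cell genes 0 passed (limma; 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone; camera adjusted p = 0.93). Hbb-bs ranged from 0.93 in the library labelled knockout 1 to 486 in knockout 2.

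Basal and spinous lists did not pass. Of 15 basal genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.951), or 6 and 5 with the replicate block. Only 1 was higher without control 2 or 3 or with quantile normalization. Their median was −0.20 and mean −0.19, while the camera direction was up. The direction of the median depended on single libraries: it was 0.14 without control 1 and 0.26 without knockout 3, but −0.73 without control 3 and −0.78 without knockout 1. Krt14 rose by 3.21 ± 0.61, or 3.85 without knockout 3, and shares sequence with Krt16 and Krt17, so its value is uncertain. Its basal partner Krt5 differed by −0.64 ± 0.44 (adjusted p = 0.282). The adhesion receptor Cd44 rose by 1.08 ± 0.26, a call lost without control 2 or 3 (0.0562 and 0.0518) and with quantile normalization (0.0615). Of 15 spinous genes 4 were higher and 3 lower, with quantile normalization 0 and 6, and with equal library totals 4 and 6 (4 and 4 adjusted over the list alone; camera adjusted p = 0.874). Without control 1, 2 were higher. Skint5 and Krt77 changed by −5.48 ± 0.40 and −3.09 ± 0.63, and Krt77 by −3.90 without knockout 3. Krt1 and Krt10, the main suprabasal keratins, differed by −0.23 ± 0.29 and −0.46 ± 0.28 (adjusted p = 0.569 and 0.219). Barrier lipid genes were higher for 12 of 32 and lower for 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0815). That list passed without control 3 or knockout 1 (0.0206 and 0.0443), and 6 members were lower without knockout 3, with equal library totals or with the replicate block, and 7 with quantile normalization, where the list median was −0.15 and not 0.45. Fa2h, a fatty acid hydroxylase, fell by 4.84 ± 0.67.

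Appendage genes were mixed. Of 21 hair placode and germ genes 3 were higher and 8 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.279), with 2 lower without control 1, 2 or 3. Krt17 rose by 4.67 ± 0.42, while Ptch1, the Hedgehog receptor, fell by 2.12 ± 0.48. Wnt targets were lower for 4 of 12 and higher for 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.206). They passed without knockout 1 (0.0334), and 2 were lower without control 1. With the replicate block 2 were higher and 7 lower, and 0 were higher with equal library totals or without control 2, control 3, knockout 1 or knockout 2. Axin2, a feedback inhibitor of the pathway, fell by 1.89 ± 0.39. Sebaceous gland genes were higher for 3 of 10 and lower for 6 (3 and 6 adjusted over the list alone; camera adjusted p = 0.2, fry adjusted p = 0.0279), with 3 lower without control 1 or 2. Hair shaft and inner root sheath genes were higher for 2 of 13 and lower for 2 (2 and 3 adjusted over the list alone; camera adjusted p = 0.687), with 4 lower under equal library totals, the replicate block or without knockout 2.

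Lists of nuclear RNA processing, the protein's own field, did not pass. Of 29 other hnRNP genes 3 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.562), with Hnrnph1 and Hnrnpd lower by −1.33 ± 0.23 and −1.02 ± 0.19. Only 1 was higher without control 2 or 3, and 1 with equal library totals, and 5 were higher with the replicate block. Of 42 splicing factors 3 were higher and 6 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.521). The lower ones numbered 15 with equal library totals, 11 with quantile normalization, 0 without control 1 or 3, 1 without control 2 and 3 without knockout 2, and 1 was higher without control 3. Of 23 genes of cohesin, CTCF and the nuclear scaffold 1 was higher and 4 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.228), or 3 and 7 with the replicate block, and 2 were higher without knockout 3. Lamin A (Lmna) rose by 1.51 ± 0.20, and the chromatin organizer Satb1 and the cohesin release factor Wapl fell by 1.24 ± 0.18 and 1.13 ± 0.18. Small nucleolar RNA hosts had 1 of 14 higher and 0 lower (0 adjusted over the list alone; camera adjusted p = 0.792), or 1 and 2 with the replicate block.

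The remaining lists did not pass camera. Camera adjusted p was 0.216 for oxidative phosphorylation (7 of 29 higher and 0 lower, 6 and 0 adjusted over the list alone), 0.221 for YAP targets (3 of 15 higher, 3 adjusted over the list alone) and 0.221 for interferon response (2 of 7 lower, 1 higher and 4 lower adjusted over the list alone). Interferon response passed fry (adjusted p = 0.00398), and 4 of its genes were lower with equal library totals, and 2 higher and 4 lower with the replicate block. It was 0.736 for periderm (1 of 5 higher, 1 adjusted over the list alone), 0.874 for the Notch pathway (1 of 11 higher, 1 adjusted over the list alone) and 0.874 for cholesterol synthesis (4 of 23 higher and 6 lower, 5 and 8 adjusted over the list alone). Oxidative phosphorylation passed without knockout 1 (0.0498), and its higher genes numbered 3, 3 and 2 without control 1, 2 and 3. YAP targets passed with knockout 1 alone (0.027), and had 6 higher without knockout 3 and 5 higher and 1 lower with the replicate block, which gave 2 higher and 1 lower for periderm, 1 and 2 for Notch and 8 and 9 for cholesterol synthesis. Cholesterol genes had 3, 2, 2, 2 and 3 lower without control 1, control 2, control 3, knockout 1 and knockout 2, and 2 higher without control 1 or knockout 2. With equal library totals 2 oxidative phosphorylation genes were higher and 2 lower, 0 small nucleolar RNA hosts higher and 1 lower, and 3 cholesterol genes higher and 9 lower.

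**Figure D3:**
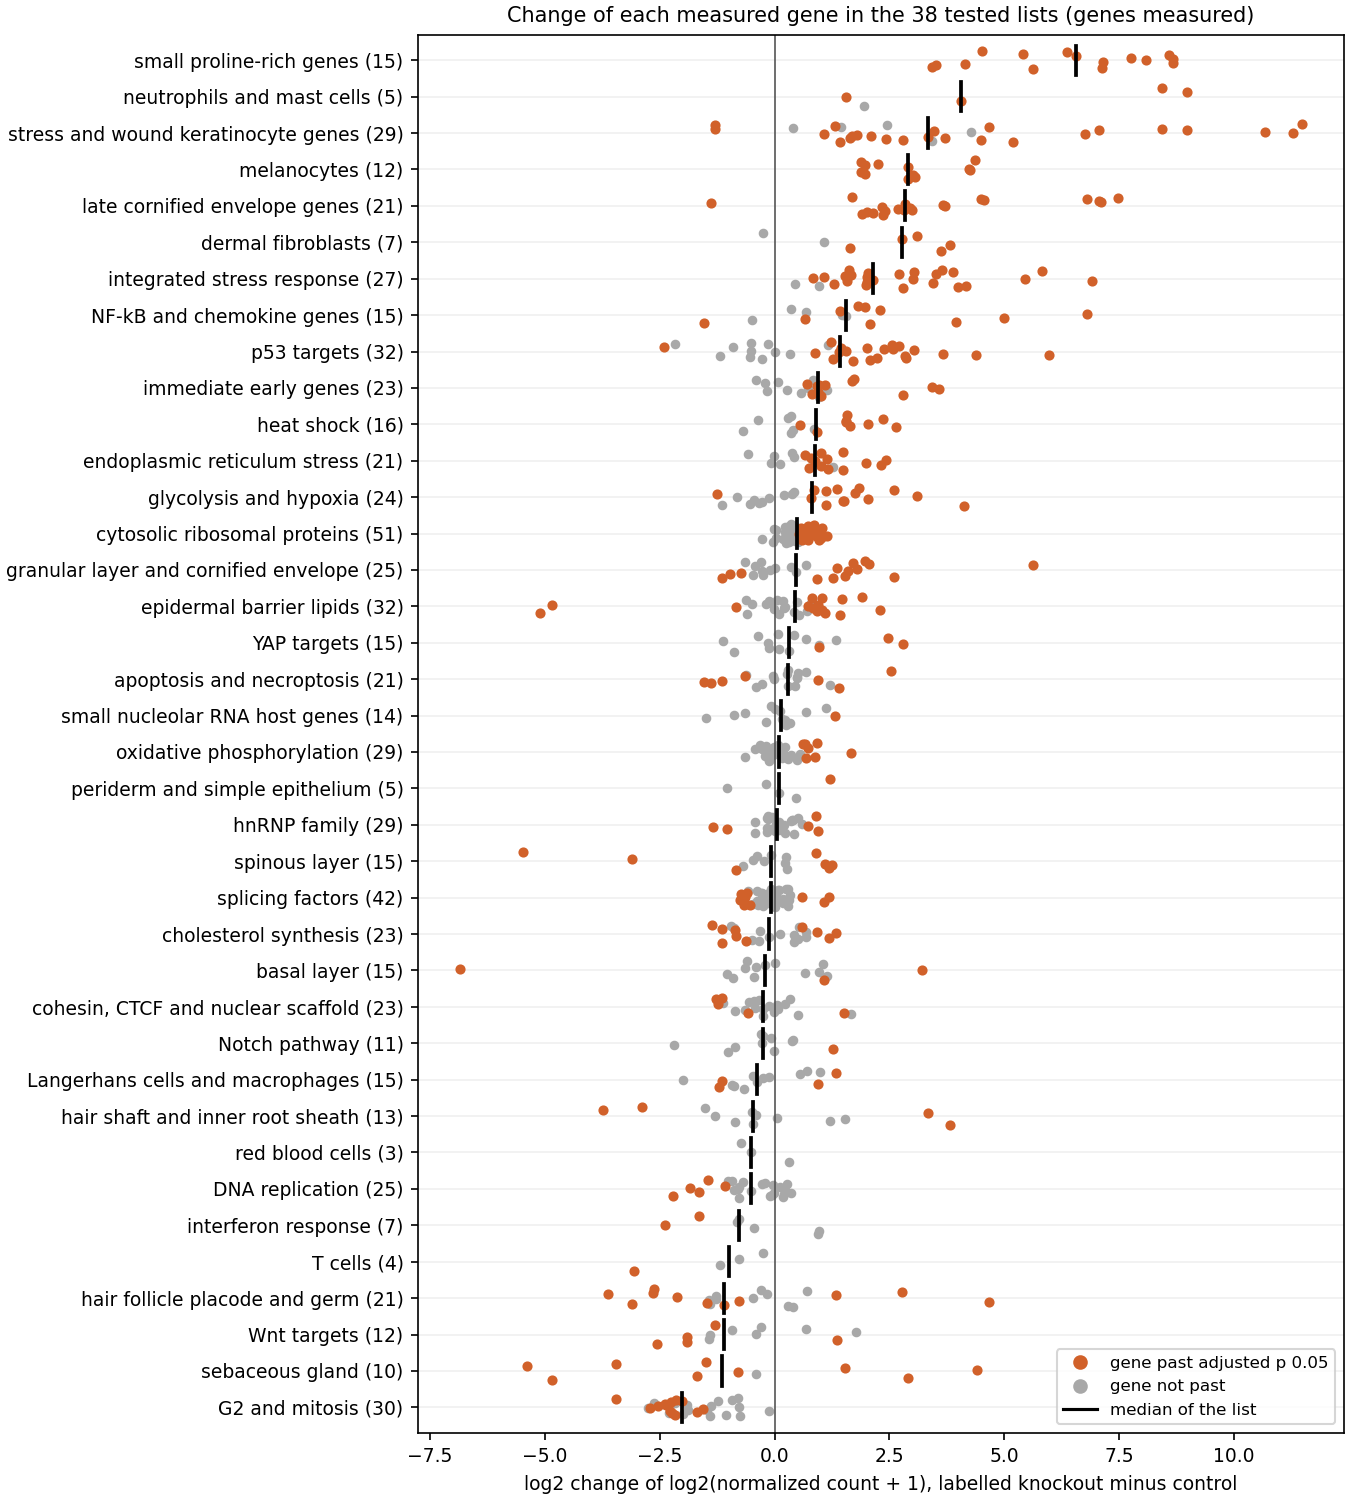
Log2 change (labelled knockout minus control, of log2(normalized count + 1)) of each measured gene in the 38 tested lists, with genes past adjusted p of 0.05 in orange, other genes in grey and the list median as a black bar. The small proline-rich genes have the highest median (6.55) and the mitotic genes the lowest (−2.01), and with equal library totals the median of all genes lies at −0.36.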

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

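Equal library totals, the test without X and Y genes and knockout 1 alone against the controls were chosen after seeing the data. Hnrnpu stayed short of the threshold in all 19 alternatives, with log2 differences from −0.351 to 0.263 and adjusted p from 0.237 to 0.996. The count of changed genes (4328) was within 1.5 times under each other scaling, filter, pseudocount, variance model, array weights and the test without X and Y genes (4174). Equal library totals moved the split to 1442 higher, with 1023 at least 2-fold higher and 2341 at least 2-fold lower, because they lower all values in the libraries with higher totals. Leaving out single libraries gave 2631 to 4464 changed genes, 1515 to 2300 higher, 1107 to 2164 lower and 1009 to 1708 at least 2-fold lower. Fewer samples are compared there, but equally few in each fit. Without 1 control 2631 to 2682 genes changed, and without 1 library labelled knockout 3250 to 4464, so sample number alone does not account for the range. Knockout 1 alone gave 2711 changed genes and 1305 higher, with the lone library assumed to vary like the controls. The replicate block gave 5781 genes, including 4327 of the 4328, and 3526 changed at least 2-fold. Among named results it changed no call except that of DNA replication. Lists past the threshold fell from 15 to 0 with the estimated correlation, and the cause was not tested. Over 158 named genes and 19 alternatives, 2800 values kept their side of the threshold, 162 lost the call, 1 gained it and 0 reversed. Of list results 786 kept it, 26 lost it, 19 gained it and 0 reversed. Count tests (edgeR and DESeq2) were planned and not run, because whole reads were not recovered. Depth and 3 libraries per group limit the detection of small changes, by how much is not known. The 24% of 2-fold changes recovered in the simulation came with far fewer changed genes, and so a stricter threshold.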

Other observations

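The tests of the 10 further gene lists, the library labels, the keratinocyte lists, keratinocyte share, scaling, dermis and sex were chosen only after the result was seen. The predictions for the splits of the libraries were also written after their counts had been seen, and that for gene span before.

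Further gene families were tested too, and none passed with an estimated correlation (camera adjusted p = 0.43 to 0.68). They overlap the fixed lists. Nars, Aars, Gars, Sars, Cars, Slc7a5, Slc7a11 and Slc3a2 are also on the integrated stress response list. Areg, Ereg and Hbegf are also on the stress and wound list, and Skint5 on the spinous list. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, 14 were higher and 0 lower (median log2 change 1.46, camera adjusted p = 1.16e-06 over the 10 further lists, and p = 0.43 with an estimated correlation). Of their 17 mitochondrial counterparts 6 were lower and 0 higher (median −0.79, adjusted p = 0.00767, and p = 0.43 with an estimated correlation). Nars rose by 3.02 ± 0.19 and Tars by 2.36 ± 0.18, while Iars2 fell by 1.28 ± 0.17. With equal library totals 13 cytosolic synthetases were higher and 1 lower. The lower mitochondrial ones numbered 3, 2, 2 and 3 without control 1, control 2, control 3 and knockout 2. Of 24 amino acid transporters 9 were higher and 7 lower, or 4 lower without control 2 or 3 (adjusted p = 0.0922 with camera and 0.00508 with fry). Slc38a1 rose by 4.45 ± 0.22 and Slc1a3 fell by 4.86 ± 0.61. Proteasome subunits were higher for 16 of 31 (median 0.62, adjusted p = 1.61e-05, and p = 0.43 with an estimated correlation). The count was 8, 9 and 10 without control 1, 2 and 3, and with equal library totals 9 were higher and 1 lower.

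Of 11 Skint genes, which are expressed in keratinocytes and bear on intraepithelial T cells, 9 were lower and Skint11 was higher (median −2.42, camera adjusted p = 3.98e-05, and p = 0.43 with an estimated correlation). Ligands of the epidermal growth factor family, which include the neuregulins Nrg1 and Nrg4, were measured for 8 members. Of these, 6 were higher and Nrg4 was lower (median 3.07, camera adjusted p = 0.0118, and p = 0.43 with an estimated correlation). The lower ones numbered 2 with the replicate block or without control 2, and 0 without control 3. Areg was higher by 5.19 ± 0.51 and Ereg by 4.49 ± 0.51. Hox genes were lower for 7 of 16 and higher for 1, Hoxb9 (median −1.48, adjusted p = 0.0118, p = 0.43 with an estimated correlation, and 0.0566 with fry), and 2, 2 and 3 were lower without control 1, 2 and 3, while the median was −0.85 without knockout 2. Imprinted genes did not pass as a list (4 of 22 higher and 6 lower, adjusted p = 0.347), yet the neighbours Igf2 and H19 fell by 3.49 ± 0.22 and 4.03 ± 0.40, while Grb10 rose by 3.67 ± 0.26. Basement membrane genes (1 of 17 higher and 5 lower, or 2 and 7 with the replicate block, adjusted p = 0.151) and clock genes (2 of 16 higher and 5 lower, or 3 lower without control 1, control 2 or knockout 2 and 8 with equal library totals, adjusted p = 0.153) did not pass camera, and clock genes passed fry (0.0372). Of the basement membrane genes 0 were higher without control 2, control 3 or knockout 1, or with equal library totals. Of the clock genes 1 was higher without control 1, control 3, knockout 1 or knockout 2, and with quantile normalization or equal library totals. These lists were chosen after the data were seen, so their p-values describe these libraries and are not independent evidence.

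Hnrnpu stood at the control level in the libraries labelled knockout, and possible explanations were examined. A single wrong group label could not account for this level in every library labelled knockout, so a check of single labels does not bear on it. Such a label would place a library nearer the other group, but the mean correlation of each library with its own group exceeded that with the other by at least 0.084. Hnrnpu reads supplied by other cell types with an intact allele would need keratinocyte genes to fall together, which stays open, since the 30 basal and spinous genes had members past the threshold in both directions and a median log2 change of −0.13 (−0.47 with equal library totals and −0.49 with quantile normalization). Reads from the part of the gene outside the deletion could not be tested and stay open: reads per exon were not analysed, and the upper end of the interval of the log2 difference, 0.45, only restates the level of the whole gene. A knockout that leaves the transcript's level as it is was not tested.

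For the 12 melanocyte genes, all higher in the libraries labelled knockout, a lower share of keratinocytes would raise markers of every other cell type alike. The median of the melanocyte list exceeded that of the 15 macrophage genes by 3.27 on the log2 scale (two-sided permutation test over genes, p = 6e-05). The smallest difference of all settings was 2.18, without knockout 1 (two-sided permutation test over genes, p = 1e-04). Other cell-type lists went both ways, however. Medians were 2.77 for fibroblasts, near the 2.90 of melanocytes, and 4.05 for neutrophils and mast cells, but −0.98 for T cells and −0.51 for red blood cells. The comparison with macrophages alone therefore cannot decide, and a lower share of keratinocytes stays open. Equal library totals moved the median of all genes from −0.02 to −0.36 only, and 12 of 12 melanocyte genes passed there (median 2.56). The rise is thus larger than the difference between these scalings. So small a shift could hardly remove the calls, so their number is no further test of scaling. Dermis left on the epidermis cannot be told apart from other sources: the 7 fibroblast genes had a median change of 2.77 (1.85 without control 3 and 3.79 without control 2), while the macrophage genes had −0.37 (0.60 without knockout 1), and dermis was removed before extraction. Of the fibroblast genes 1 is also on another list, as is 1 of the melanocyte genes, and Col1a1 reached at most 192 normalized counts. A larger number of melanocytes or more transcripts per melanocyte may underlie the pattern, and these were not tested.

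Xist was high in the libraries labelled knockout 2 and 3 (5656 and 4758 normalized counts) and at most 3.27 in a control. If the sex of the animals accounted for the calls, the library labelled knockout 1 would resemble the controls. Of 3735 genes outside X and Y called without that library, it lay outside the range of the controls on the side of the call in 94.5%, against 25.2% on average and 26.6% at most for 100 simulated unchanged libraries. Among 4188 genes called with it, where it is part of the call, the share was 99.7%. A contribution of sex to single genes other than Xist and the Y-linked ones stays open.

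A hypothesis written before its result was seen held that genes with a longer genomic span are lower in the libraries labelled knockout. Across 12749 genes, which are not independent replicates, Spearman's rho of the log2 change against span was −0.077 (permutation test, p = 1e-05, the smallest that 100000 permutations can give), short of the bound of −0.1. It was −0.075 with GC content held fixed. The median change was 0.29 for the shortest 10% of genes and −0.13 for the longest 10%.

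The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4328 genes and the highest other 0, and at least 2-fold changes gave 3067 and 0, so 1 split reached each count. Each other split mixes controls with libraries labelled knockout, so the difference between these widens the spread within its groups. A count of 0 there is therefore no reference for chance. For lists the real split gave 15 and the highest other 22, and 3 splits reached 15. Of the 4 splits that part all 3 pairs of adjacent animal numbers, those other than the real one gave 10 to 14 lists and 0 genes. The 6 splits that keep 2 pairs together gave 11 to 22 lists.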
